A study of Lactiplantibacillus plantarum with 6 samples.

How the data were processed

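Transcript levels of Lactiplantibacillus plantarum strain WCFS1, a lactic acid bacterium, were measured on 6 two-colour DNA microarrays. Per the labels, cultures growing in a chemically defined medium received sodium L-lactate, and RNA was taken at 15, 30 and 60 min. Each array set one of these samples against RNA taken at t=0. Each time has 2 arrays, named replicate L and replicate R; the series design calls the duplication biological, and the labels do not say what L and R stand for. The labels place t=0 RNA in the Cy5 channel and the time point in the Cy3 channel on all 6 arrays, with no dye swap recorded.

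The deposited scanner files hold spot and local background intensity per channel on a linear scale, quantified with ImaGene, with channel 1 named Cyanine 3 and channel 2 Cyanine 5 per the file headers. These intensities are neither background-corrected nor normalized. Each array has 10807 spots, of which 9553 carry a locus tag of the strain, for 2851 tags. A deposited value table holds log2 ratios of the same arrays. Set against the scanner values, they proved to be log2 of Cy3 over Cy5, with slopes of 0.982 to 1.003 and r of 0.984 to 0.999 over spots. Their column medians were 0.0128, 0.0141 and 0.00738 for replicate L at 15, 30 and 60 min and 0.0103, 0.00275 and 0.00217 for replicate R. The authors' way of normalizing that table is not given in the sources used here, and its direction rests on the same dye labels.

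Median net intensity over the gene spots was 428 to 596 in Cy3 and 293 to 537 in Cy5, over local backgrounds of about 475. Between 94.6% and 98.8% of gene spots were well above background, taken as a spot mean over the background mean by more than 2 background standard deviations. No spot was saturated. The number of arrays limits the precision. Spots that ImaGene marked with flag 3 for quality, 161 to 210 gene spots per array, were left out.

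Ratios were computed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, each array was normalized by loess with the 1254 control and other spots at weight 0, spots of one probe were averaged, and probes of a gene were averaged. The 2819 tags with a value on all 6 arrays were tested; the other 32 were not. All 6 arrays entered one limma fit with a coefficient per time, followed by eBayes, and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. A ratio against 0 is the test, so the spread of the t=0 samples has no term of its own. Per the labels the arrays of a replicate share the same t=0 sample. The fit treats them as independent, which its p-values do not allow for. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. The design, the lists and the rule for named genes were fixed before the data were examined, as were the alternatives other than those named as added later.

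Under the labelled dyes, 3 of the arrays run opposite to the other 3, so the direction of the ratios is not settled. Every comparison is therefore given as labelled and on a turned reading, in which the sign is turned on the 3 arrays that correlate below -0.3 with the 15 min array of replicate L over the gene probes (replicate L at 60 min and replicate R at 30 and 60 min). The turned reading was chosen after the correlations were seen. It was selected because it makes the arrays run together, so its p-values are too favourable, and its overall sign follows the labelled dyes of the 3 arrays left as they were.

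On data simulated with the gene-wise spread of the turned reading, with 200 of 2819 genes changed, the test at 15 min recovered 78% of genes changed by a log2 of 0.5, 96% of those changed by 1 and 100% of those changed by 2. The tests at 30 and 60 min recovered 70% and 68% of those changed by 0.5, 96% and 92% of those changed by 1, and 100% of those changed by 2, with 13, 12 and 6 false calls at 15, 30 and 60 min. With the spread of the labelled reading, the test at 15 min recovered 64%, 86% and 98%, that at 30 min 56%, 86% and 97% and that at 60 min 62%, 84% and 97%, with 11, 9 and 9 false calls. The changed genes were drawn at random, so their spread did not depend on their change. As labelled, the opposing arrays give a gene that responds a large spread. The tag lp_0104, for example, had a mean of 5.69 at 15 min as labelled and an adjusted p of 0.448 by limma. The recovery given for the labelled reading does not hold for such genes. The simulated arrays also varied independently of each other. In the data, the differences of replicate L minus replicate R on the turned reading correlated at 0.882 between 15 and 60 min, so recovery and false calls there can differ.

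The probes carry locus tags and no gene symbols. None of the tags (0 of 2851) matched the gene table at hand, which describes assembly ASM991365v1 of another strain with 3031 genes. Of 28 fixed gene lists, 26 rest on symbols and were not analysed here; the 2 lists given by locus tag, both of the lactate racemase region, were tested. Their tags come from general knowledge of the strain and are paired with names by neither the files nor the gene table. Named genes were to be, at each time, the 10 largest rises and 10 largest falls among genes that passed the test with the same sign in both replicates, or, where fewer than 5 passed, the 5 largest with a log2 ratio of at least 1 in both, and all members of the lactate racemase lists. Because tags have no names here, the text prints few of the others. Runs of neighbouring tags, at least 3 tested genes with number gaps of at most 3, a mean log2 ratio of at least 1 and one sign on both arrays of a time, were sought after the data had been seen.

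Alternatives covered the background correction, the normalization, the deposited log2 table, a filter on dim probes, the probe summary, the replicate as a block, fits of single times, robust and trended eBayes, and each array left out. The turned reading with all its alternatives, flag 3 spots kept and a dye term were added after the data were seen.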

Results

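RNA from L. plantarum WCFS1 was compared between cells sampled 15, 30 and 60 min after addition of sodium L-lactate and cells sampled at t=0, just before it. The data comprised 6 two-colour arrays, 2 for each time, named replicates L and R. Median net intensity over the gene spots of an array was 428 to 596 in the Cy3 channel and 293 to 537 in the Cy5 channel. A value is given below as the mean log2 ratio of time point over t=0 ± SD over the 2 arrays of a time (n = 2), and the adjusted p-values come from limma. Whether each array holds the time point of its label was not settled, so times are given as labelled.

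The direction of the ratios was not settled by the dye labels. With the dyes as labelled, the arrays of replicate L at 15 and 30 min and of replicate R at 15 min correlated positively with one another over genes, as did the arrays of replicate L at 60 min and of replicate R at 30 and 60 min, with r from 0.587 to 0.861. Every pair that joined these sets had a negative r, from -0.923 to -0.517, and the 2 arrays of 30 min had an r of -0.88. Genes are not independent replicates, and these r describe the arrays only. All comparisons are therefore given as labelled and with the sign turned on the arrays of replicate L at 60 min and of replicate R at 30 and 60 min, called the turned reading. The turned reading was chosen after the correlations were seen, which makes its p-values too favourable.

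**Figure D1:**
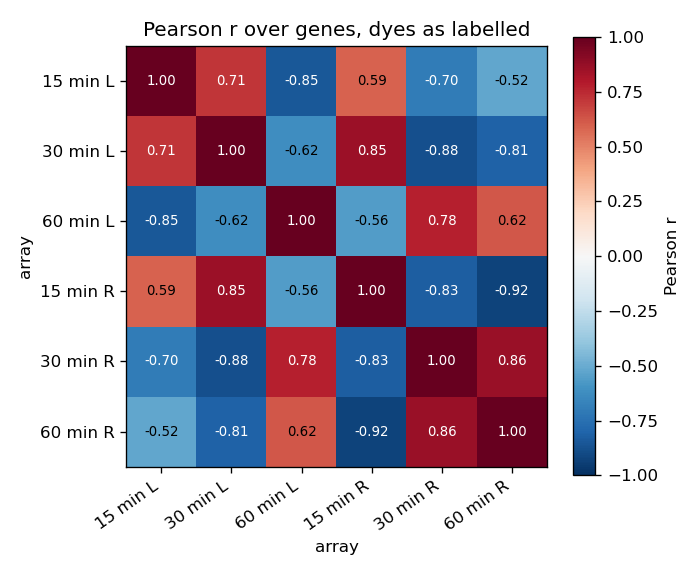
Pearson correlation over genes between the log2 ratios of each pair of arrays, with the dyes as labelled; both axes list the 6 arrays by time and replicate, and colour gives r from -1 to 1. Correlations are positive within 2 sets of 3 arrays and negative between them, down to -0.923.

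Among tested tags, the 3 largest ratios on each array, in absolute size, belonged to lp_0104, lp_0105 and lp_0109 of the lactate racemase operon list. The files do not pair these tags with gene names; the tags of this list and of the regulator and nickel uptake list were assigned from general knowledge of the strain. Lactate racemase is a nickel-dependent enzyme that interconverts L- and D-lactate. On the turned reading, all 4 tested members of the lactate racemase operon list (lp_0104, lp_0105, lp_0107 and lp_0109) rose at each time, with list medians of 5.57 at 15 min, 5.37 at 30 min and 5.68 at 60 min. The tag lp_0104 rose by 5.69 ± 0.43 at 15 min, 5.48 ± 0.42 at 30 min and 5.75 ± 0.98 at 60 min, which are 51.7-fold, 44.6-fold and 53.8-fold. The tag lp_0109 rose by 5.63 ± 0.36, 5.32 ± 0.12 and 5.75 ± 0.27 at the same times. The lowest of the 4 at 15 min, lp_0107, rose by 4.76 ± 0.59. The tag lp_0106 lacked a value on the 30 min array of replicate L and was not tested; it read 4.84 to 6.69 on the other arrays. The tag lp_0108 had no probe among the spots.

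The list of the lactate racemase regulator and nickel uptake, tags lp_0100 to lp_0103, also rose on the turned reading in all 4 members at each time, with medians of 3.19, 3.13 and 3.43. Its largest member was lp_0101, at 3.64 ± 0.09 at 15 min, 3.46 ± 0.07 at 30 min and 3.89 ± 0.28 at 60 min. Its smallest was lp_0100, at 2.07 ± 0.01, 1.88 ± 0.02 and 2.29 ± 0.38. Both channels of these genes were well above background on all 6 arrays, counted where any spot of the gene was. Adjusted over the list alone, 4 of 4 members of each list passed at each time as well. By camera at the preset correlation, the operon list had adjusted p-values of 2.17e-10, 1.53e-10 and 1.8e-10 at 15, 30 and 60 min, and the other list 5.5e-10, 1.8e-10 and 2.17e-10. The estimated correlation was 0.82 for the operon list and 0.86 for the other, far above the preset 0.01, so these p-values are too favourable. With the estimated correlation all 6 adjusted p-values were 0.0441. Without background subtraction the operon medians were 4.10, 3.79 and 4.34 and those of the other list 2.38, 2.15 and 2.61, so the fold changes depend on the background correction. With a dye term, lp_0104, lp_0107 and lp_0100 no longer passed at 15 min (adjusted p = 0.0956, 0.0663 and 0.0956) or at 60 min (0.0611, 0.0555 and 0.0611). Their ratios stayed about as large, at 5.39, 4.94 and 2.08 at 15 min and 6.05, 5.15 and 2.27 at 60 min, while their standard errors grew from 0.34, 0.26 and 0.12 to 0.53, 0.41 and 0.20. The term also leaves 2 residual degrees of freedom instead of 3, so these calls ended through lower precision; the means at 30 min and over the 3 times, which hold both orientations equally, do not change with it.

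With the dyes as labelled, the same genes had opposite signs on different arrays. The operon list had medians of 5.57 at 15 min, 0.08 at 30 min and -5.68 at 60 min, and the regulator and nickel uptake list 3.19, -0.06 and -3.43. By camera at the preset correlation the adjusted p-values of both lists were 0.00632 at 15 and at 60 min and 0.993 at 30 min. With an estimated correlation they were 0.363 at 15 and 60 min and 0.997 at 30 min. No single member passed, over all genes or adjusted over the list alone (0 of 4 in each list at each time). The smallest adjusted p-value among these genes was 0.418.

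**Figure D2:**
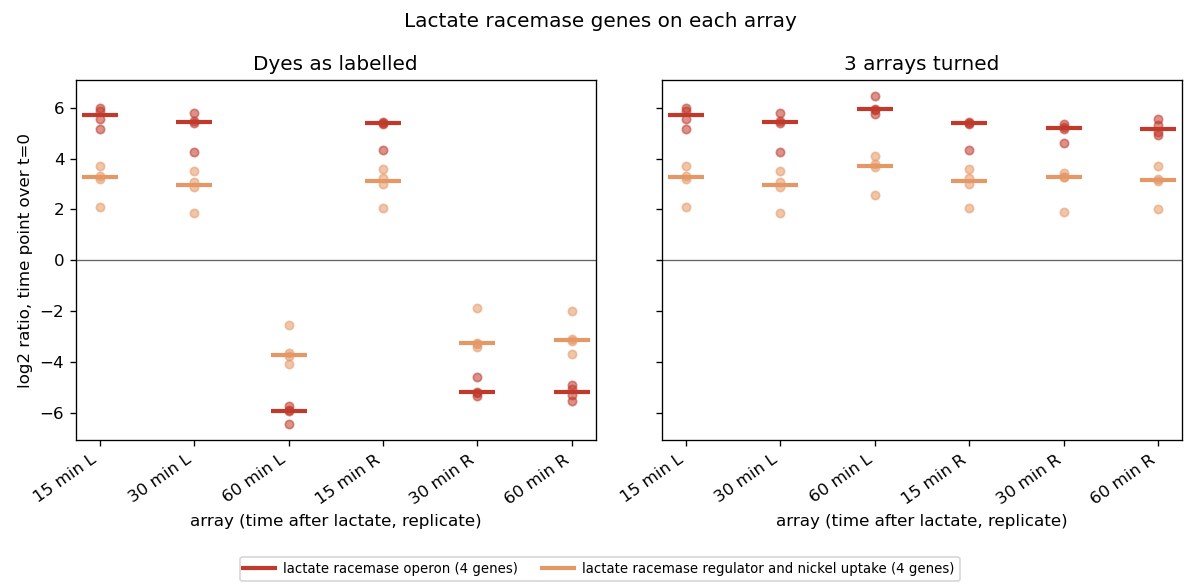
Log2 ratio of time point over t=0 (vertical axis) of the tested lactate racemase genes on each of the 6 arrays (horizontal axis), with the dyes as labelled (left) and with 3 arrays turned (right); points are genes and bars are medians over the 4 genes of a list. As labelled, the genes lie above 0 on 3 arrays and below 0 on the other 3; with 3 arrays turned, lp_0104 lies between 5.05 and 6.45.

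At 15 min against t=0, outside the lactate racemase region, the tag lp_3256 fell by 1.96 ± 0.03 on the turned reading (adjusted p = 0.00112) and lp_1836 rose by 1.01 ± 0.04 (adjusted p = 0.00276). The call of lp_1836 at 15 min was lost with a dye term (1.10, adjusted p = 0.0635, with a standard error of 0.087 instead of 0.072) and with the 15 min arrays fitted alone (0.0758). Without background subtraction lp_3256 stood at -1.31. The 3 neighbouring tags lp_0575 to lp_0577 fell together, with a regional median of -1.54 ± 0.49, and all 3 passed. None of these 3 passed with a dye term (median of the gene means -1.50 against -1.54, median standard error 0.26 against 0.16), with the 15 min arrays fitted alone or without either array of 30 min, and 1 passed without replicate R of 15 min. The 4 tags lp_0927 to lp_0930 had a regional median of 1.41 ± 0.67, of which 1 passed (adjusted p = 0.0493). None passed with a dye term (median of the gene means 1.49 against 1.39, median standard error 0.43 against 0.26). None passed either without background subtraction, with median centring, with the probe median or with the 15 min arrays fitted alone. With scaling between arrays or the replicate block 3 passed, and with robust and trended eBayes 2. The median of the gene means was 0.94 without replicate R of 15 min and 1.88 without replicate L. The single call also depended on both 30 min arrays, which enter it only through the shared spread. The 12 tested tags from lp_1670 to lp_1682 had medians of -0.81 in replicate L and -4.49 in replicate R; none passed, and the smallest adjusted p-value was 0.12. In all, 88 of 2819 genes were called at 15 min on the turned reading, 37 higher and 51 lower. With the dyes as labelled, 0 genes were called by limma and 306 had an unadjusted p under 0.05; 14 were called without either array of 30 min and 9 with the 15 min arrays fitted alone. The mean ratios at 15 min are the same on both readings, and the shared estimate of the spread differs. The turned count fell to 9 when the 15 min arrays were fitted alone, and it was 6 with a dye term. It was 19 without replicate L and 12 without replicate R of 15 min, 14 without either array of 30 min and 54 without either array of 60 min.

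At 30 min against t=0, lp_3256 fell by 2.28 ± 0.34 on the turned reading (adjusted p = 0.000665) and lp_1836 rose by 1.05 ± 0.13 (adjusted p = 0.00224). Without background subtraction lp_3256 stood at -1.26. All 3 tags of lp_0575 to lp_0577 fell again, with a regional median of -1.11 ± 0.02. None of the 3 passed with a dye term (median of the gene means -1.09 in both fits, median standard error 0.18 against 0.16), without background subtraction (-0.82), or without either array of 30 min or of 60 min. The tags lp_0927 to lp_0930 had a regional median of 1.21 ± 0.15 and none passed, whereas all 4 passed with the turned 30 min arrays fitted alone and 3 without either array of 15 min. The run from lp_1670 to lp_1682 had medians of -3.51 in replicate L and -3.12 in replicate R. None of its 12 tags passed (smallest adjusted p = 0.0973), whereas all 12 passed with the turned 30 min arrays fitted alone. That fit holds 2 arrays, 1 of them turned so that it runs with the other, and takes its spread largely from all genes. Its calls are therefore too favourable, here and for lp_0927 to lp_0930. The turned reading called 55 genes, 26 higher and 29 lower. As labelled, 0 genes were called by limma and 40 had an unadjusted p under 0.05, and 34 genes read at least 1 in opposite directions on the 2 arrays; 6 were called without replicate L and 4 without replicate R of 30 min. Fitted alone, the turned 30 min arrays gave 352 genes; without background subtraction the count was 20, 13 higher and 7 lower, with robust and trended eBayes 89, and with a dye term 12. It was 6 without replicate L and 4 without replicate R of 30 min, 36 without either array of 15 min and 22 without either array of 60 min; lp_1836 did not pass without either 30 min array (adjusted p = 0.0553 without replicate L and 0.081 without replicate R), nor did lp_0104 (0.138 and 0.081), lp_0107 (0.0883 and 0.0884) or lp_0100 (0.141 and 0.116). The tags lp_0102 and lp_0103 did not pass without replicate R of 30 min (0.0588 and 0.0541).

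At 60 min against t=0, lp_3256 fell by 2.54 ± 0.03 on the turned reading (adjusted p = 0.000343), and stood at -1.64 without background subtraction. All 4 tags of lp_0927 to lp_0930 rose, with a regional median of 1.60 ± 0.53. All 3 tags of lp_0575 to lp_0577 fell, with a regional median of -1.50 ± 0.28. None of these 7 tags passed with a dye term or without either array of 30 min or of 60 min; with the 60 min arrays fitted alone none of the 4 and 2 of the 3 passed, and without background subtraction none of the 4 (median of the gene means 1.47). With the dye term the medians of the gene means were 1.49 against 1.59 for the 4 and -1.43 against -1.46 for the 3, with median standard errors of 0.43 against 0.26 and 0.26 against 0.16. The run from lp_1670 to lp_1682 had medians of -0.75 in replicate L and -3.89 in replicate R, and none of its 12 tags passed (smallest adjusted p = 0.155). The turned reading called 88 genes, 55 higher and 33 lower. As labelled, each mean ratio at 60 min has the opposite sign, so that lp_3256 stood at 2.54 ± 0.03; 0 genes were called by limma and 324 had an unadjusted p under 0.05; 15 were called without either array of 30 min and 15 with the 60 min arrays fitted alone. The turned count was 15 when the 60 min arrays were fitted alone, 53 after scaling between arrays, 142 with robust and trended eBayes and 6 with a dye term. It was 10 without replicate L and 13 without replicate R of 60 min, and 15 without either array of 30 min.

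**Figure D3:**
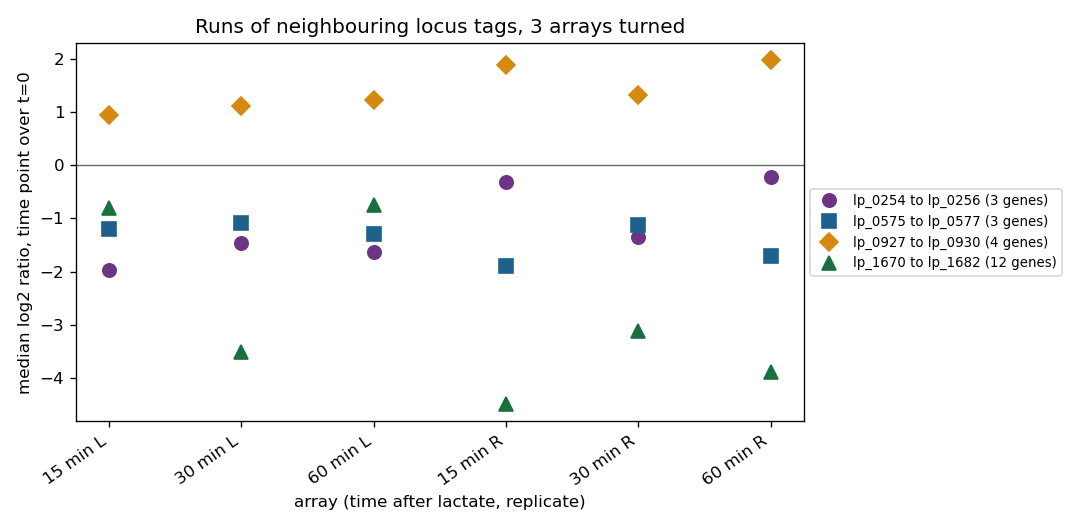
Median log2 ratio of time point over t=0 (vertical axis) over the tested genes of 4 runs of neighbouring locus tags on each array (horizontal axis), with 3 arrays turned. The run from lp_1670 to lp_1682 lies between -4.49 and -3.12 on 4 arrays and at -0.81 and -0.75 on the 15 and 60 min arrays of replicate L.

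Over the 3 times together, the turned reading called 180 genes at any time, 88 with a higher and 92 with a lower mean, and the labelled reading 0 by limma, with 219 at an unadjusted p under 0.05; without replicate L or R of 30 min the labelled count was 12 or 11. The 8 tested tags of the lactate racemase region, all 3 tags of lp_0575 to lp_0577 and all 4 of lp_0927 to lp_0930 were among the 180; none of lp_1670 to lp_1682 was, though 7 of its 12 tags passed without replicate L of 15 min. The calls of lp_0575 to lp_0577 and lp_0927 to lp_0930 were all lost with a dye term, which left the medians of their means at -1.31 and 1.40, or without either array of 30 min, and only 1 of the 4 tags lp_0927 to lp_0930 passed without background subtraction, as also without replicate R of 60 min. A dye term cannot change a mean over the 3 times, since both orientations count equally there. The tag lp_3256 fell with an adjusted p of 0.000156 and lp_1836 rose with 0.00062. Of the 180 genes, 167 had one sign on all 6 turned arrays, 83 above 0 and 84 below, which is 92.8%, against 25.5% of all tested genes; the choice of arrays to turn and the test itself both favour genes with one sign. With a dye term the count was 16. Without replicate R of 15 min it was 61, without replicate L or R of 30 min 12 and 11, and without replicate L or R of 60 min 47 and 38.

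Between times, no lactate racemase gene passed the test on the turned reading. The operon list differed by a median of -0.26 between 30 and 15 min, 0.12 between 60 and 15 min and 0.35 between 60 and 30 min, with adjusted p-values by camera of 0.206, 0.308 and 0.0814 at the preset correlation and of 0.617 each with an estimated correlation. The last passed at the preset correlation under several other settings, for example without background subtraction (0.46, adjusted p = 0.0225). The regulator and nickel uptake list differed by -0.18, 0.23 and 0.41, and the last had an adjusted p of 0.0239 at the preset correlation and an adjusted p of 0.617 with an estimated correlation. At the preset correlation that list did not pass without replicate L of 60 min (0.13, adjusted p = 0.292) or replicate R of 30 min (0.40, adjusted p = 0.14). No gene was called in any of the 3 contrasts on the turned reading; by limma 0 passed, with 141 between 30 and 15 min, 206 between 60 and 15 min and 173 between 60 and 30 min at an unadjusted p under 0.05. With the dyes as labelled, the operon list differed by -5.42, -11.25 and -5.76 and the other list by -3.34, -6.62 and -3.28, each with an adjusted p of 0.00313 at the preset correlation and 0.23 with an estimated correlation. Without replicate L of 30 min the labelled operon differences were -10.86 between 30 and 15 min and -0.54 between 60 and 30 min, and those of the other list -6.47 and -0.30. Without replicate R of 30 min they were -0.12 and -11.13 for the operon and -0.16 and -6.41 for the other list; the 2 between 30 and 15 min did not pass there (adjusted p = 0.393 and 0.17). Again 0 genes were called by limma as labelled, with 81, 546 and 68 at an unadjusted p under 0.05, although between 60 and 15 min the 4 members of each list passed when adjusted over the list alone. The labelled contrast of 60 and 15 min called 132 genes when only those 4 arrays were fitted, and also without either array of 30 min; 13 genes differed between 30 and 15 min without replicate L of 30 min and 17 between 60 and 30 min without replicate R of 30 min.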

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

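The tests of the channels, of the 30 min arrays, of the difference between replicates, of the pairs of arrays and of the dye effect were all chosen after the results they bear on were seen.

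With the dyes as labelled, the lactate racemase lists differed between times by camera at the preset correlation (adjusted p = 0.00313 for each difference). With an estimated correlation no difference passed (adjusted p = 0.23), nor did any by fry (adjusted p of 0.24 to 0.297). The operon list differed by -5.42 between 30 and 15 min, -11.25 between 60 and 15 min and -5.76 between 60 and 30 min, and the regulator and nickel uptake list by -3.34, -6.62 and -3.28. These differences follow the 3 arrays that run opposite to the rest. A response that reversed at the same time in both replicates is argued against by the duplicates of 30 min, which had an r of -0.88 over genes. A reversal after 30 min in replicate L and before 30 min in replicate R would give the same signs. It would leave t=0 RNA in Cy5 on every array, which the r of the Cy5 channels given below argues against. Exchanged channel files are argued against by the Pro25G control spots, whose median log2 ratio of Cy3 over Cy5 stayed positive on the 3 opposing arrays, at 1.22 or more, as it did on the others, provided that these spots take their signal from a fixed dye. RNA exchanged between the dyes on the 3 arrays, a swap the labels do not record, remains a candidate explanation and was not settled. The channels that would then hold t=0 RNA correlated over genes at 0.986 or more on all pairs. The highest r between a t=0 and a time channel was 0.967, and the channels labelled t=0 went down to 0.947. The arrays to turn were chosen by their opposite ratios, which favours this ordering. Opposite ratios alone do not say which channel changed. With t=0 RNA in Cy5 on all 6 arrays, the Cy5 channels would stay alike whatever the response did. Their r, down to 0.947, argues against that labelling, although it comes from the same intensities as the ratios. The channels that would then hold the time points correlated at 0.960 to 0.991.

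On the turned reading, the regulator and nickel uptake list differed between 60 and 30 min by a median of 0.41 (adjusted p = 0.0239 by camera at the preset correlation, adjusted p = 0.617 with an estimated correlation).

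Also on the turned reading, 4 genes stood at 1 or more in replicate L and at -0.5 or less in replicate R at both 15 and 60 min: the neighbouring tags lp_0168 to lp_0171, chosen after their values were seen. The difference was not tested for these genes alone. Over all tested genes, 0 passed a comparison of the replicate L arrays with the replicate R arrays. That comparison takes in the 30 min arrays, where these genes did not differ in this way. The tag lp_0170 read 3.33 at 15 min and 3.75 at 60 min in replicate L, -1.50 and -1.38 in replicate R, and 0.56 and 1.19 at 30 min in replicates L and R. The run from lp_1670 to lp_1682 also stood apart on the 15 and 60 min arrays of replicate L.

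More widely, on the turned reading the 15 and 60 min arrays correlated over genes at 0.849 in replicate L and 0.923 in replicate R, against 0.587 between the 15 min arrays and 0.619 between the 60 min arrays; the 30 min arrays correlated at 0.879. The differences of replicate L minus replicate R correlated over genes at 0.882 between 15 and 60 min, but at -0.0683 between 15 and 30 min and -0.212 between 30 and 60 min. A constant difference between the replicates is argued against, since the difference at 30 min followed the mean of the others with a slope of -0.073 (95% bootstrap interval over genes -0.096 to -0.0499), where such a difference needs a slope near 1. Arrays that hold another time point than their label remain possible and were not settled: of the 15 ways to split the 6 turned arrays into 3 pairs, the labelled times called 0 genes and the highest other split 91, the pairs being the 15 and 60 min arrays of replicate L, both 30 min arrays, and the 15 and 60 min arrays of replicate R. Each of these pairs joins an array left as labelled with a turned one. Their r as labelled, -0.849, -0.879 and -0.923, were the most negative of all pairs of arrays, and what this pairing reflects was not tested. Such a split points to a structure of the samples, but it restates the correlations above and was the highest of 15, so it is no separate test. The splits, 15 in number, are too few for a share under 0.05, and no split can give fewer genes than the 0 of the labelled times, so nothing about chance follows from their counts. A replicate that responded at another pace would be a biological alternative and was not tested.

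For the 180 genes called at any time on the turned reading, an effect of the dyes on single genes was examined as the whole change. The 30 min mean holds 1 array of each orientation, so such an effect cancels there and would leave it near 0. In the direction of the 15 min mean, the 180 genes had a median 30 min mean of 0.375 (95% bootstrap interval over genes 0.343 to 0.405), against 0.41 at 15 min. The test that called these genes includes the 30 min mean and favours values away from 0, so this value is no separate evidence. The 16 genes at 1 or more one way on both 15 min arrays, chosen without the 30 min arrays, had 3.32 (1.88 to 4.24), against 3.08. For these 16, a dye effect as the whole change is argued against. They are genes of large change, among them the 8 tested lactate racemase tags, and do not stand for the 180. Genes are not independent, so these intervals are too narrow. The means at 30 min and over the 3 times do not change with a dye term. A dye effect in part of the 15 and 60 min ratios stays open, because each of these times holds a single orientation. Estimated from the 30 min arrays, it enlarged the 15 min ratio of 49.4% of the 180 genes and reduced the rest, and genes whose 30 min arrays agree are favoured by the test. With a dye term 16 genes were called; the term leaves 2 residual degrees of freedom instead of 3 and widens the standard errors at 15 and 60 min of most genes named here.

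Classes of probes outside the locus tags had median net signals, averaged over both channels and all arrays, above the highest of the negative control spots at 34.7, although single spots of mtf and antilp lay lower, down to 24.2 and 32.1. The median was 370 for probes named mtf, 450 for THI, 1210 for RFN, 883 for SRP and 39.8 for antilp.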

How the results depend on the processing

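The turned reading, the dye term, the kept flag 3 spots and all alternatives on the turned reading were added after the data were seen. The Agilent processed signals were not run because the files come from ImaGene, and the slide block was not run because the files name no slide or scan. Unless a value shows it, the cause of a change was not tested. As labelled, each count of called genes was 0. It stayed 0 without background subtraction, with median centring, scaling between arrays, the deposited log2 values, the dim-probe filter, the probe median, robust and trended eBayes and flag 3 spots kept. With the replicate as a block all 7 labelled counts were 0 too; on the turned reading the block gave 90, 58, 82 and 157 genes at 15, 30, 60 min and any time, against 88, 55, 88 and 180, and 0 in each contrast. On the turned reading the L minus R differences correlated at 0.882 between 15 and 60 min, but at -0.0683 and -0.212 with 30 min, so the letters tied the 15 and 60 min arrays and did not pair all 3 times.

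Fits of the compared arrays alone gave, as labelled, 9 genes at 15 min, 15 at 60 min and 132 between 60 and 15 min. Turning 3 arrays gave 88, 55, 88 and 180 genes, operon medians of 5.37 at 30 min and 5.68 at 60 min and a regulator list median of 3.43 at 60 min, the last 2 reversed. The differences between times became -0.26, 0.12 and 0.35 for the operon and -0.18, 0.23 and 0.41 for the regulator list (30 minus 15, 60 minus 15, 60 minus 30), reversed in the contrasts with 60 min. Leaving out each array gave, as labelled, 0 to 14, 0 to 6, 0 to 15 and 0 to 12 genes at 15, 30, 60 min and any time, and 0 to 13, 0 to 132 and 0 to 17 in the contrasts. The operon median at 30 min ranged from -5.21 to 5.45 and that of the regulator list from -3.28 to 2.97; the differences between 30 and 15 min ranged from -10.86 to -0.12 and from -6.47 to -0.16, and those between 60 and 30 min from -11.13 to -0.54 and from -6.41 to -0.30. An array left alone in its time was assumed to vary like the others.

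On the turned reading, both list medians against t=0 kept their sign and passed by camera at the preset correlation under every alternative run. Counts moved to 20 at 30 min without background subtraction, 53 at 60 min with scaling between arrays, 9, 352 and 15 at 15, 30 and 60 min with the compared arrays alone, 89 and 142 at 30 and 60 min with robust and trended eBayes, and 6, 12, 6 and 16 with a dye term. Leaving out each array gave 12 to 54, 4 to 36, 10 to 68 and 11 to 122. For the operon between 60 and 30 min, where the adjusted p with all 6 arrays was 0.617 at an estimated correlation, camera at the preset correlation passed without background subtraction (0.46), with the deposited values (0.44), the replicate block (0.35), the compared arrays alone (0.35), flag 3 spots kept (0.43) and a dye term (0.54), and ranged from 0.060 to 0.79 with an array left out. Between 60 and 15 min the operon list passed at the preset correlation with the deposited values (0.43) and ranged from -0.13 to 0.58. At an estimated correlation its adjusted p by camera with all 6 arrays was 0.617 there too. Between 30 and 15 min the operon list ranged from -0.54 to 0.035. The regulator list between 60 and 30 min did not pass with scaling between arrays (0.23) and ranged from 0.13 to 0.65; between 60 and 15 min it ranged from -0.026 to 0.50. The genes named and the tested tags of the runs were well above background in both channels on all 6 arrays. For the genes named, any spot of a gene sufficed for this. The size of the larger ratios depended on the background correction.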

Other observations

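Tags with the prefix lp_p3, 38 of them tested, had medians slightly above 0 on the turned reading. These were 0.21 ± 0.18 at 15 min, 0.13 ± 0.02 at 30 min and 0.23 ± 0.12 at 60 min (SD over 2 arrays). Of the 38, 3 were called at any time, all 3 higher. That is a similar share to the 180 called among all 2819 tested genes. The run lp_0254 to lp_0256 had medians of -1.96 and -1.64 at 15 and 60 min in replicate L, -0.32 and -0.22 in replicate R, and -1.46 and -1.36 at 30 min in replicates L and R. None of its 3 tags passed at 15, 30 or 60 min (smallest adjusted p = 0.163 at 30 min) or over the 3 times together (0.122). All 3 passed with the turned 30 min arrays fitted alone, a fit of 2 arrays whose calls are too favourable. On the turned reading, the channels taken as t=0 correlated over genes with a median r of 0.993 within a replicate (6 pairs) and 0.993 between replicates (9 pairs).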
